A study of Homo sapiens with 3 samples.

How the data were processed

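Gene expression was measured in xenograft tumours of TE-2, an established esophageal cancer cell line, grown under the skin of nude mice. Total RNA from the tumours was labelled with Cy3 and hybridised to a 1-colour Agilent array, per the labels' protocols. The 3 arrays were of 3 groups with 1 array per group: saline vehicle, 4-methylhistamine (4MH, an agonist of the histamine H4 receptor) and JNJ7777120 (JNJ, an antagonist of the same receptor). Per the labels, both compounds were injected into a vein daily at 100 µM/kg for 4 weeks. That unit is printed as the labels give it, a concentration per body weight, so the amount injected is uncertain. The labels' protocols also speak of 4 groups while describing 3, and call the animals rats once and mice elsewhere. Groups were taken from the sample titles and treatment labels, and whether an array held RNA of 1 tumour or of several is not given in the sources used here. The 3 arrays came from 1 scan image per the file headers, so no slide or scan separates the groups.

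The deposited scanner files hold fluorescence intensity per spot from Agilent Feature Extraction 11.0.1.1, per the file headers and the submitters' processing notes. The processed intensity was background-subtracted and spatially detrended within each array, per the file headers. The headers give an average of 0.9997 for the multiplicative detrending surface of the 4MH array and 0.9994 for that of the JNJ array, and 0 for the vehicle array. The headers annotate the probe design on the human build hg19, and the labels give a human organism, whereas the series' design text describes a mouse array. The file headers were followed. The authors also deposited a table of log2 values for the same arrays, with the normalization method not given in the sources used here. Its medians were 4.61 on the 4MH array, 4.61 on the vehicle array and 4.61 on the JNJ array, and the correlation with the log2 scanner intensity exceeded 0.9999 on each array, so scale and direction were known. Its differences between arrays correlated at 0.99997, 0.99998 and 0.99997 with those from quantile normalization of the processed intensity, and the median absolute difference was at most 0.0005. Results from that table and from quantile normalization are thus nearly the same result and not separate ones. Of the probes in the scanner files, 6 had no value in that table as used here.

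For the main setting, log2 of the processed intensity was taken minus the 75th percentile of each array over non-control probes. Control spots (1439 per array), 60 negative-control probes and spots that Feature Extraction marked as non-uniform or population outliers were left out. Spots of 1 probe were averaged on the log2 scale. A probe counted as measured on an array when at least 0.5 of its kept spots were well above background. Negative-control spots passed that mark in 9.17% of 360 cases on the 4MH array, 11.4% on the vehicle array and 12.5% on the JNJ array, so a passing mark does not exclude background signal. A probe measured on 1 array of a pair has a bound only: the bright value against the higher of the dim probe's own value and the lowest value among measured probes of the dim array.

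Of 60924 non-control probes, 60904 carry the maker's identifiers, which the files do not pair with gene names. The other 20 carry RefSeq accessions, and all 20 matched a human gene symbol through a RefSeq table of assembly GRCh38.p14, used for names only. Results of 2 of these genes are not reported here, and summaries of named genes leave them out. No coordinates are printed, since that assembly is not the build of the array. The analysis had been planned per gene and was made per probe for this reason. The rule for named genes took, per comparison, up to 10 higher and 10 lower genes with a symbol, measured on both arrays, in the brighter upper part of the measured probes, not saturated, and at least 2-fold apart in the main setting, with normexp background correction and with quantile normalization. It added up to 4 members of each gene list with the largest log2 ratio, histamine receptors whatever their values, and at most 2 probe identifiers per direction where symbols are lacking. The remaining genes among those reported, and all control probes, were named after their values were seen.

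With 1 array per group there are no residual degrees of freedom, so no p-value was computed, and the paired t-test with random variance model of the series' design text could not be run. Its 2-fold threshold was kept. Technical spread within an array was taken from probes with at least 6 spots. Across array and probe pairs, the median standard deviation between spots was 0.23 (log2) up to an intensity of 50, 0.09 from 50 to 500, 0.03 from 500 to 5000 and 0.02 above. Errors given for ratios combine the standard deviations between spots of both arrays. They leave out differences between animals and technical differences between arrays, such as those of labelling and hybridisation. They are thus not the full technical error of a ratio. The number of arrays limits the precision of every comparison.

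The count of probes was tested on simulated data of 33856 probes with assumed spot noise of 0.31, 0.16 and 0.04 (log2, dim to bright), above the median values given here. Of 200 changed probes, 8 were recovered at a true 1.5-fold change, 180 at 2.5-fold and 197 at 4-fold, and 186, 207 and 196 unchanged probes were called. For the relation between both treatment comparisons, the arrays were exchanged at random within each probe 100 times. The exchanges keep the size of the observed differences, including any effect of treatment, and change only which array they belong to. They give the 3 arrays equal spread, which holds the correlation near 0.50, and do not give the covariance or shared counts of unchanged groups. A 95% interval came from 100 bootstrap resamples of probes.

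Before the data were examined, 31 gene lists and the alternatives were fixed. The alternatives were quantile normalization, centring on the median, the authors' deposited log2 values, other filters on dim probes and a 3-fold threshold. Chosen after seeing the data were normexp (offset 50) on median spot and background intensities, because the planned mean intensity is not a column of the files used here, cyclic loess, local background subtraction alone, and removal of the median of each block of 32 by 16 spots. Tools were R 4.3.3 with limma 3.58.1 for normexp, quantile and cyclic loess normalization, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.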

Results

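The data collected were 3 arrays of a human probe design, 1 per group, from TE-2 xenograft tumours of mice given saline vehicle, 4MH or JNJ. The share of signal that came from mouse host cells in the tumours was not analysed here. Each array held 62903 spots and 60924 non-control probes. Of these probes, 32054 (52.6%) were well above background on the 4MH array, 33637 (55.2%) on the vehicle array and 32820 (53.9%) on the JNJ array, and 29554 were so on all 3. The 75th percentile of intensity was 182 on the 4MH array, 222 on the vehicle array and 188 on the JNJ array. No replicates were analysed here, so each difference is one between single arrays, given with the standard deviation between repeated spots where a probe has them.

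The first comparison, named in the series' design text, asked which transcripts differ between tumours of mice given the H4 receptor agonist 4MH and those given vehicle. PGK1, the glycolytic enzyme phosphoglycerate kinase, was lower with 4MH, at an intensity of 476 ± 8.58 (SD, 10 spots) against 2450 ± 36.5 with vehicle, a log2 ratio of −2.08 ± 0.03 or 4.22-fold after scaling. ARHGDIA had a log2 ratio of −1.35 ± 0.04, and PRMT1, an arginine methyltransferase that acts on histones and RNA-binding proteins, had −1.09 ± 0.02. The actin-binding protein gene PFN1 stood at −0.88 ± 0.02 and the histone H3.3 gene H3-3A at −0.72 ± 0.05. Each gene was set beside the 1000 measured probes nearest in brightness, whose median ratios went from −0.22 (for PGK1) to −0.42 (for ARHGDIA). Of those probes, 1.4% were lower than PGK1, 4.8% than ARHGDIA, 7.4% than PRMT1, 11.3% than PFN1 and 21.7% than H3-3A. The small spread between spots therefore does not set the last of these genes apart from probes of like brightness.

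Of the 17 reported genes with a symbol that were measured, 3 were at least 2-fold lower with 4MH, 0 were 2-fold higher and 14 lay within 2-fold, with a median log2 ratio of −0.23. The calls for ARHGDIA and PRMT1 ended under quantile normalization, at −0.92 and −0.72. The authors' deposited log2 values, which nearly repeat that normalization, had −0.93 and −0.73. The PGK1 call held in both and with normexp. Only 3 of the 31 gene lists had any member among the named probes, and none reached the minimum of 5, so no list was tested. From the hypoxia and glycolysis list, PGK1 was lower while GAPDH, the glycolytic dehydrogenase, had −0.23 ± 0.02, a sign that turned with cyclic loess. From the ribosomal protein list, RPS18 had 0.22 ± 0.03, RPLP1 0.16 ± 0.04 and RPL10 0.00 ± 0.07 (RPS18 0.05 under quantile normalization and 0.50 under cyclic loess), and from the oxidative phosphorylation list COX4I1, a subunit of cytochrome c oxidase, had −0.14 ± 0.03. The signs of RPLP1, RPL10 and COX4I1 turned with the scaling, as did those of the cytoskeletal genes ACTB (0.03) and DYNLL1 (−0.26), the polyamine synthesis gene ODC1 (−0.21), and EIF3D, MTX1 and RACK1. Several of these probes were very bright. RPS18 read 338732 with 4MH and 356007 with vehicle, near the highest intensities on those arrays (374698 and 402905). RPLP1, ACTB, COX4I1 and GAPDH were bright too (GAPDH 226831 and 324255). No spot was flagged as saturated, but whether ratios of such bright probes are compressed was not tested. Ratios near 0 at these probes therefore do not show stable expression. GRM4, a glutamate receptor gene, was not well above background on any of the 3 arrays. No probe of the files used here carried a name from the list of histamine receptors and metabolism.

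Control probes named for human PGK1 were lower with 4MH as well, with log2 ratios of −1.63 for the probe named _3 and −2.47 for the probe named _5. The human GAPDH control probes had −0.45 for the probe named _3 and −1.27 for the probe named _5. In both genes the probe named _5 was further down, by −0.85 for PGK1 and −0.82 for GAPDH. In the authors' deposited log2 values, the GAPDH control probes had −0.38 (_3) and −0.87 (_5) and the PGK1 control probes −1.43 (_3) and −2.30 (_5).

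**Figure D1:**
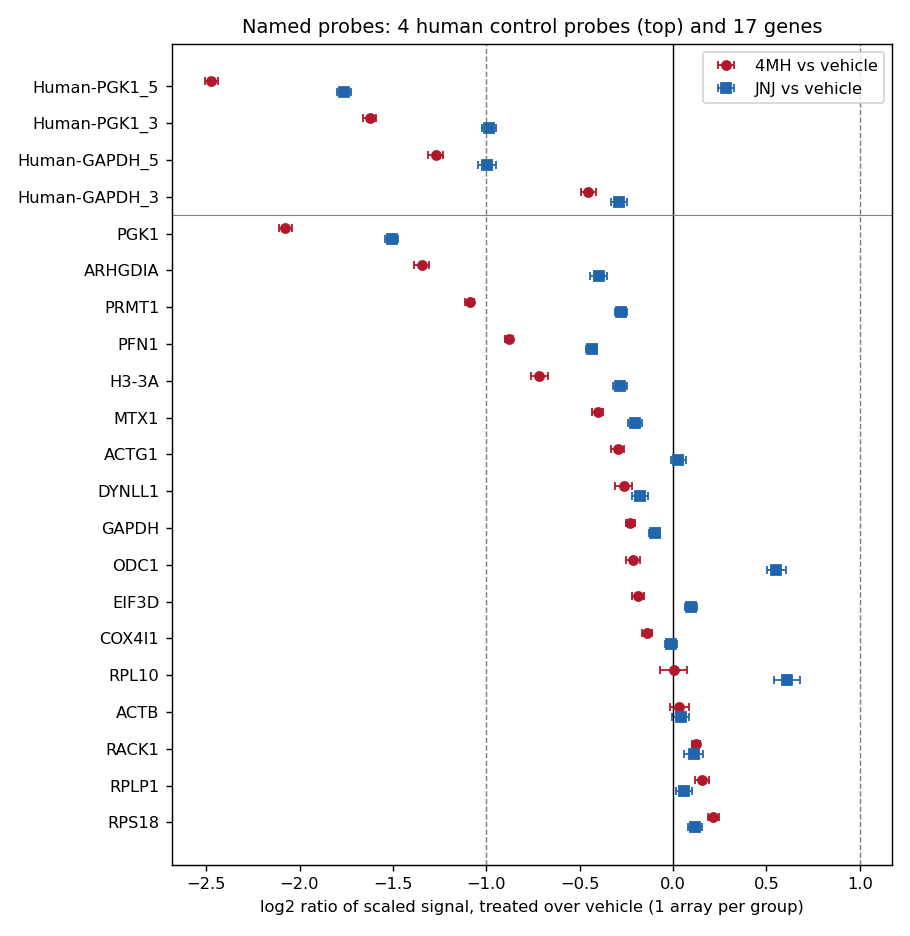
Log2 ratio of scaled intensity to vehicle (x axis) for 4 human control probes and the 17 reported genes with a symbol that were measured (y axis). Points are single arrays, red circles for 4MH and blue squares for JNJ, error bars are the combined standard deviation between spots, and dashed lines mark 2-fold. PGK1 lies at −2.08 with 4MH and −1.51 with JNJ, while genes such as ACTB, RPLP1 and COX4I1 lie near 0 and turn sign with the scaling in both comparisons.

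Across all probes measured on both arrays (30397), 2115 were at least 2-fold higher and 2038 at least 2-fold lower with 4MH, together 13.7%. Cyclic loess normalization moved that split to 2541 higher and 1379 lower, and normexp to 1066 and 1491, with 905 and 1477 among the brighter probes only. At 4-fold, 436 were higher and 264 lower. A further 1614 probes were measured on the 4MH array only, 638 of them with a bound of at least 2-fold, and 3209 on the vehicle array only, 313 of them with such a bound. Among probes without a gene name that the rule took, ASHGV40059635 was lower with 4MH, at a log2 ratio of −9.59 (771-fold) and intensities of 50.5 against 47538 with vehicle, followed by ASHGV40001384 at −7.87 (145 against 41596). ASHGV40040808 was higher at 5.44 (15709 against 441) and ASHGV40021067 at 5.35 (2391 against 71.4). With normexp, ASHGV40059635 had −8.47 (355-fold) and ASHGV40021067 4.43. Spot noise at its median level would give 11 probes past 2-fold, and at its highest level 517. H3-3A was −0.33 under quantile normalization and PFN1 −0.58 under cyclic loess.

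The second comparison, of the H4 receptor antagonist JNJ with vehicle, asked the same question of receptor blockade. PGK1 was lower again, at 730 ± 14.7 against 2450 ± 36.5, a log2 ratio of −1.51 ± 0.04 or 2.84-fold. RPL10, a protein of the large ribosomal subunit, had 0.61 ± 0.07 and ODC1, the first enzyme of polyamine synthesis, 0.55 ± 0.05. The RPL10 probe was dim, at 241 with JNJ against 186 with vehicle, where the RPS18 probe had 327260 and 356007. With normexp its ratio was 0.46. Of the 1000 measured probes nearest in brightness, 86.7% had a lower ratio than RPL10 and 90% a lower ratio than ODC1. PFN1 had −0.44 ± 0.03, ARHGDIA −0.40 ± 0.05, H3-3A −0.29 ± 0.04 and PRMT1 −0.28 ± 0.03. Under quantile normalization ARHGDIA had −0.24, H3-3A −0.16 and PRMT1 −0.17. Of the probes nearest in brightness, 1.1% were lower than PGK1, 16% than PFN1, 26.7% than ARHGDIA, 31.4% than PRMT1 and 31.5% than H3-3A.

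Of the same 17 genes, 0 were at least 2-fold higher with JNJ, 1 was 2-fold lower (PGK1) and 16 lay within 2-fold, with a median of −0.01. GAPDH had −0.10 ± 0.03, RPS18 0.12 ± 0.04, RPLP1 0.06 ± 0.04 and COX4I1 −0.01 ± 0.03, and the signs of RPS18, RPLP1, COX4I1, ACTB (0.04) and ACTG1 (0.03) turned with the scaling, while GAPDH ranged from −0.15 in the authors' deposited values to −0.00 under cyclic loess. The human PGK1 control probes had −0.98 for the probe named _3 and −1.76 for the probe named _5, and the human GAPDH control probes −0.29 and −0.99.

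Over 31030 probes measured on both arrays, 1425 were at least 2-fold higher and 1195 at least 2-fold lower with JNJ, together 8.44%, beside 625 and 642 with normexp. At 4-fold, 168 were higher and 105 lower. Probes measured on the JNJ array only numbered 1748 (420 with a bound of at least 2-fold), and those measured on the vehicle array only 2576 (439). ASHGV40032349 was higher at a log2 ratio of 7.70 (4159 against 23.6 with vehicle) and ASHGV40040808 at 7.29 (58500 against 441). ASHGV40001384 was lower at −7.07 (263 against 41596) and ASHGV40050065 at −6.02 (33.6 against 2575). The lower intensities of ASHGV40032349 and ASHGV40050065 are near the dimmest measured probe of their array (19.2 and 16.2), and normexp gave 5.74 and −4.70, so the sizes of these ratios depend on the background. Spot noise at its median level would give 12.4 probes past 2-fold, and at its highest level 579.

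Set directly against JNJ, the 4MH array had none of the 17 genes past 2-fold in either direction in the main setting. The lowest was ARHGDIA at −0.95 ± 0.06, followed by PRMT1 at −0.81 ± 0.02, ODC1 at −0.77 ± 0.05, RPL10 at −0.61 ± 0.08 and PGK1 at −0.57 ± 0.04, and none of them exceeded 0.10. ODC1 was −0.50 under quantile normalization, PGK1 −0.38 under cyclic loess and RPL10 −0.45 with normexp. Of the probes nearest in brightness, 7.7% were lower than ARHGDIA, 10.3% than PRMT1, 14.9% than ODC1, 14.3% than RPL10 and 23.8% than PGK1. The signs of GAPDH, RPLP1, COX4I1, MTX1, RACK1, ACTB and DYNLL1 turned with the scaling. Of 30103 probes measured on both arrays, 1624 were at least 2-fold higher and 1685 at least 2-fold lower with 4MH, together 3309 probes. More were higher than lower under quantile normalization (1701 and 1459) and under cyclic loess (1735 and 1319). The authors' deposited log2 values, which nearly repeat quantile normalization, gave 1695 and 1462. Fewer were higher than lower with normexp (624 and 1003) and among the brighter probes only (575 and 1079). Probes measured on the 4MH array only numbered 1908 (637 with a bound of at least 2-fold), and those on the JNJ array only 2675 (324). ASHGV40052459 was higher with 4MH at a log2 ratio of 5.10 (2619 against 78.8) and ASHGV40005655 at 4.19 (5925 against 335). ASHGV40059635 was lower at −8.63 (50.5 against 20717) and ASHGV40032349 at −7.63 (20.2 against 4159), the latter close to the dimmest measured probe of the 4MH array (19.4). With normexp, these had −7.45 and −5.63, and ASHGV40052459 4.31.

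The ratios of the 4MH array also depended on brightness. The Spearman correlation across probes between ratio and brightness was −0.23 for 4MH against vehicle, 0.00 for JNJ against vehicle and −0.26 for 4MH against JNJ, and −0.00, 0.01 and −0.01 after quantile normalization. Probes are not independent replicates.

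**Figure D2:**
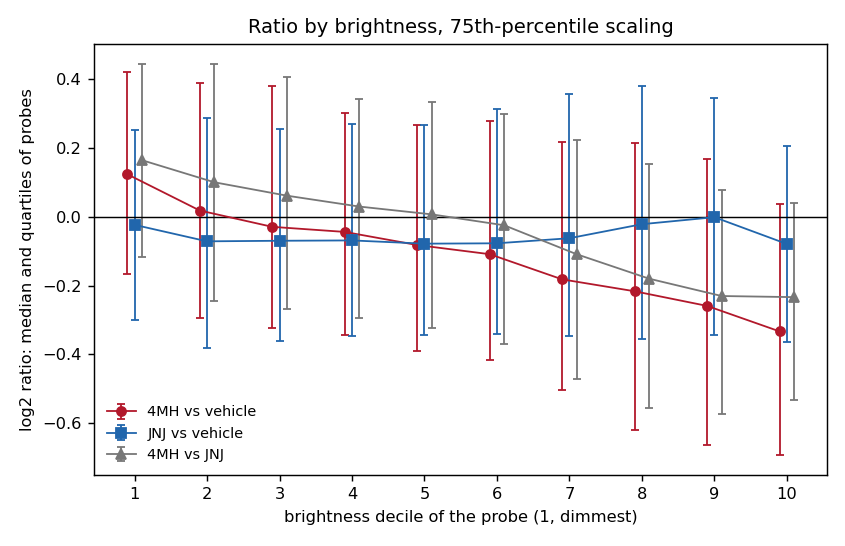
Log2 ratio (y axis, median and quartiles of probes) in 10 groups of probes ordered by brightness (x axis, 1 the dimmest) at 75th percentile scaling. For 4MH against vehicle the median went from 0.12 in the dimmest group to −0.33 in the brightest and for 4MH against JNJ from 0.16 to −0.23, whereas JNJ against vehicle showed a Spearman correlation of 0.00.

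The agonist and the antagonist were also compared through their ratios to the same vehicle array. At its RefSeq probe, PGK1 was past 2-fold lower in both, and the difference between the treatments was −0.57 ± 0.04. The brighter human PGK1 control probe named _3 (247055 against 2450 with vehicle) had −1.63 with 4MH and −0.98 with JNJ. Its value with JNJ was thus within 2-fold in the main setting and past it with normexp (−1.04), so that call depends on the probe. Across 29554 probes the Pearson correlation of both ratios was 0.54 (95% bootstrap interval over probes 0.53 to 0.56), beside 0.50 (0.48 to 0.52) from exchanging arrays at random within each probe. The covariance was 0.247 beside 0.229 (0.218 to 0.242). At least 2-fold higher with both compounds were 660 probes, beside 577 (511 to 630) from the exchanges and 92.8 for independent lists, and 502 were lower with both, beside 572 (534 to 618) and 77.6. Opposite directions were seen in 9 probes higher with 4MH and lower with JNJ and in 29 the other way, beside 34.6 and 33.6 from the exchanges and 77.9 and 92.5 for independent lists. The single vehicle array cannot be split, so part or all of the excess over independent lists may come from the shared control. The array standing apart from the other 2 was 4MH for 37.1% of probes, vehicle for 34.5% and JNJ for 28.4%, beside 33.3% (32.7% to 34.0%) for vehicle from the exchanges.

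**Figure D3:**
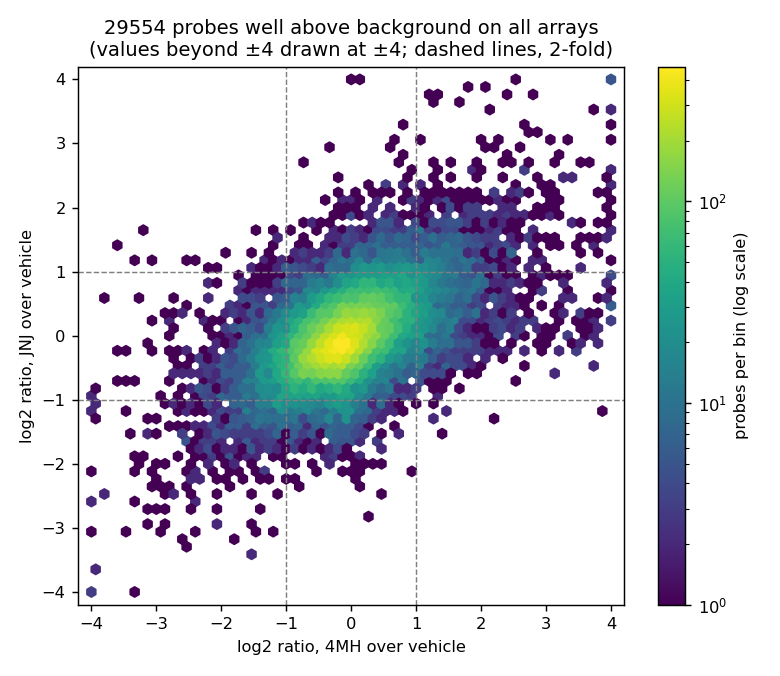
Log2 ratio to vehicle with 4MH (x axis) and with JNJ (y axis) for 29554 probes measured on all 3 arrays. Colour gives the number of probes per hexagon on a log scale, dashed lines mark 2-fold, values beyond ±4 are drawn at ±4, and the cloud runs along the diagonal with a correlation of 0.54, beside 0.50 from random exchange of arrays.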

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

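Normexp background correction, cyclic loess, local background subtraction alone and block medians were chosen after the result was seen; the other settings were planned. Counts of 2-fold probes are given in the order 4MH against vehicle, JNJ against vehicle, 4MH against JNJ. Beside 4153, 2620 and 3309 in the main setting, normexp gave 2557, 1267 and 1627, with 41.7%, 49.3% and 38.4% of them higher; the cause was not tested. Filters changed which probes entered: 6580, 4978 and 5839 with probes well above background on at least 1 array, 9947, 8571 and 9544 with no filter, and 2382, 1316 and 1654 in the brighter upper part only, where 38.0%, 50.2% and 34.8% were higher, beside 50.9%, 54.4% and 49.1% in the main setting. A 3-fold threshold left 1372, 641 and 881. Counts stayed within 1.5 times of the main ones under quantile normalization (3917, 2521 and 3160, of which 3511, 2490 and 2830 were shared with the main setting), median centring, the authors' log2 values, cyclic loess, local background subtraction and block medians. Quantile normalization gave 59.5%, 56.9% and 53.8% higher. Cyclic loess moved the median ratio of 4MH to vehicle by 0.11 and its share of higher probes from 50.9% to 64.8%.

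The correlation of both treatment ratios, 0.54, was 0.58 with normexp, 0.52 with probes well above background on at least 1 array, 0.51 with no filter and 0.59 in the brighter upper part; the cause was not tested. Over the 6 settings that can move a single gene against the others, 179 of 306 values of named genes moved by more than the spread between spots and 127 by less. Of values past 2-fold, 0 changed sign, but in the main setting only 3, 1 and 0 genes were past 2-fold in the 3 comparisons. Among all 17 measured genes, the sign turned with the scaling for 10, 5 and 7. The PGK1 calls at its RefSeq probe held with normexp, quantile normalization and cyclic loess. Not run were the median over a gene's probes, the shifts of gene lists, normexp on mean intensities and the methods' t-test with random variance model. No paired analysis was possible because each group has 1 array. Signal over background limits dim probes: the spot standard deviation has a median of 0.23 (log2) up to an intensity of 50, against 0.02 above 5000.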

Other observations

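The tests of RNA integrity, of the brightness trend and the uneven surface behind the larger 4MH count, and of the shared vehicle array were chosen after the result was seen; those of the brightness trend for PGK1, of spot noise and of single animals were not, except that cyclic loess was added to the PGK1 test after the data were seen. What the test of RNA integrity required was also widened after its values were seen, so it decides nothing on its own.

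Among control probes, the one named ETG05_66023, whose target is not given in the sources used here, had an intensity of 1066 with vehicle, 55.4 with 4MH and 189 with JNJ, log2 ratios of −3.99 and −2.26. With normexp these ratios were −3.04 and −1.98. The probe ETG05_36762 of the same series had 0.11 and −0.02. Mouse-named PGK1 control probes had log2 ratios of −2.48 (_3) and −2.40 (_5) with 4MH and −1.97 and −1.55 with JNJ. The rat-named GAPDH probe _5 gave 52552 with vehicle, 15903 with 4MH and 21726 with JNJ, while the rat-named PGK1 probe _3 was not well above background on any array. The specificity of these probes was not analysed here, so signal at them was not taken to identify the species of a transcript. The bright corner spots gave 28681 with vehicle, 15860 with 4MH and 13275 with JNJ, log2 ratios to vehicle of −0.57 and −0.88 after scaling. The control probe ERCC-00062_278 had −0.02 ± 0.07 with 4MH and −0.89 ± 0.09 with JNJ, and 0.87 ± 0.08 for 4MH against JNJ. Some control probes thus differed between arrays by as much as many named genes, well beyond the spread between spots.

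PGK1 was lower on both treated arrays at its RefSeq probe and at both human control probes. A trend of ratios with brightness is argued against as the whole cause: after quantile or cyclic loess normalization the ratio nearest to 0, over both treatments, was −1.49, with quantile normalization. Shorter or less intact RNA on the treated arrays stays open. The human PGK1 probe named _5 was lower than the one named _3 by −0.85 with 4MH, and human GAPDH had −0.82, which such a loss could give. In the authors' deposited values with 4MH, GAPDH had −0.38 (_3) and −0.87 (_5), a smaller gap than that of PGK1 (−1.43 and −2.30). The rat-named GAPDH pair went the same way (−0.45 at _3 and −1.44 at _5 with 4MH, −0.52 and −1.04 with JNJ). Its _3 probe was dim, at 39.9 with 4MH, 66.1 with vehicle and 39.3 with JNJ, and had −0.11 and −0.15 with normexp. The mouse-named GAPDH pair went the other way (−1.17 and 0.08, −0.72 and −0.16), with a dim _5 probe (138 with 4MH, 159 with vehicle and 121 with JNJ). The mouse-named PGK1 pair also went the other way in the main setting (−2.48 and −2.40, −1.97 and −1.55). In the authors' deposited values that pair turned with 4MH (−2.22 at _3 and −2.33 at _5) but not with JNJ (−1.91 and −1.51). The human PGK1 probe named _3 was lower than that of GAPDH by −1.17 with 4MH and −0.70 with JNJ. The positions and specificity of these probes and integrity values were not analysed here. A response of PGK1 to either compound, or a difference between animals, is likewise untested with 1 array per group.

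More probes were 2-fold apart for 4MH than for JNJ against vehicle (a ratio of 1.59, from 1.16 with no filter on dim probes to 2.02 with normexp over 11 settings; 2.14 at a 3-fold threshold). The brightness trend is unlikely to be the whole cause, since the ratio was 1.47 with cyclic loess, and so is uneven signal across the surface, since it was 1.59 with block medians removed. The highest spot noise would give a difference of −61.7 probes, against 1533 observed. That noise was pooled over the 3 arrays and applied alike to each comparison, so the difference cannot show whether the 4MH array was noisier. At its highest level it would give 517 probes in all for 4MH against vehicle, fewer than 1533. That value covers only noise between spots within an array, so noisier labelling or hybridisation of the 4MH array stays open. A difference between single animals unrelated to treatment cannot be told apart from an effect of 4MH, since there is 1 array per group.

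The ratios with the agonist and with the antagonist had the same sign for 69.1% of probes, beside 66.6% (66.0% to 67.3%) for randomly exchanged arrays. Probes 2-fold lower with both compounds (502) were fewer than in the exchanges (534 to 618), and those higher with both (660) were more (511 to 630). The covariance of 0.247 exceeded the mean of randomly exchanged arrays by 0.0176 and lay above their range (0.218 to 0.242). The correlation (0.545) also lay above its range of 0.482 to 0.520. With looser filters it was 0.518 (36419 probes well above background on at least 1 array) and 0.508 (60837 probes, no filter). The range was made on 29554 probes and not on these larger sets, so it is no reference for them. The exchanges treat probes as independent, so their range cannot show whether the excess is chance. Part or all of the covariance could come from the shared vehicle array. Noise between spots alone would give a covariance of 0.0139 and 0.49 probes past 2-fold in the same direction, but the chance values of the vehicle sample itself cannot be measured from 1 array. A shared response to both compounds was not tested.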
